A study of Homo sapiens with 18 samples.

How the data were processed

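RNA from 18 LNCaP cultures was sequenced after capture with an RNA exome kit, per the labels' protocols. The groups were 3 siRNA pools (control, SRF, Nkx2-5) by vehicle or 5 nM R1881, with 3 libraries each, taken from the sample titles. The authors deposited 1 table of whole-number read counts for 58037 Ensembl genes and 18 libraries, and the values are raw counts with no normalization. Per the submitters' processing notes, CASAVA 1.8.2, TopHat2 2.0.13, Picard 1.97 and HTSeq 0.6.1 were used with the genome build GRCh38 (hg38). The role of each tool, the gene annotation, and whether the counting used strand are not given in the sources used here. Capture by exome probes means that levels of different genes are not directly comparable and that noncoding RNA is seen only in part. Reads that match near-identical genes may be dropped or split by such counting, and duplicates without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

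Gene symbols were those of the deposited table, and a symbol on more than 1 ID (292 symbols) was kept apart by ID. Positions, gene types and transcript sequences came from GENCODE release 29 by gene ID, which held 57433 of the 58037 IDs and not the other 604. Genes were kept with edgeR's filterByExpr by group, which left 16690. Library sizes were the counts over the kept genes, scaled by TMM factors, and the total counts per library were 13550541 to 22925125. A gene with 0 counts in a library can be as high as 3 counts (0.131 to 0.221 CPM by library), and a fold against a group at 0 was taken against 3 counts over the group. A fold against 1 to 3 counts was given as a ratio of counts per total count, with an exact 95% counting interval. Neither used the TMM factors.

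A quasi-likelihood model (edgeR 4.0.16, R 4.3.3) with 6 group means over all 18 libraries left 12 residual degrees of freedom, with a biological coefficient of variation of 5.63% and 11.05 prior degrees of freedom. Contrasts gave 3 R1881 effects, 4 siRNA effects and 3 differences of R1881 effects. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum. Log2 CPM used a prior count of 2, and log2 fold changes were those of the fitted model with edgeR's default prior count. In simulated counts for the SRF siRNA effect in vehicle over 16690 genes, the step recovered 95 of 100 genes changed 1.5-fold and 100 of 100 changed 2-fold, and called 9 of 16490 unchanged genes. Levels are TMM-normalised CPM as mean ± SD.

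Before the data were examined, 19 gene lists were fixed: androgen-induced and androgen-repressed genes, actin cytoskeleton genes bound by SRF with MRTF, immediate early genes bound by SRF with TCF, cardiac genes regulated by NKX2-5, DNA replication, mitosis, cholesterol synthesis, fatty acid synthesis, unfolded protein response, interferon response, p53 targets, luminal, basal, neuroendocrine, fibroblast and smooth muscle, and leukocyte markers, mitochondrially encoded transcripts and ribosomal protein genes. The androgen lists rest on general knowledge of LNCaP cells and not on these samples. Each list was tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over 190 tests of lists and contrasts, and again with an estimated correlation. Counts of members are given after adjustment over all genes and over the list alone. The rule for named genes, also fixed then, took the siRNA targets, the 8 largest rises and 8 largest falls among called genes with an average of at least 50 counts in the higher group, a gene symbol and non-overlapping groups, and up to 3 members per list with the smallest adjusted p. For differences of R1881 effects the rule asked for 50 counts in the highest group and for no separation of groups. Some genes that the rule names, and a test that needs 1 of them, are not reported here.

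The size of the R1881 response was scored as the mean log2 CPM of genes called at least 2-fold in the siRNA arm not compared, fitted without the other libraries, and on the preset androgen lists. The value given is the ratio of responses. Its p comes from the difference of the responses, by an exact two-sided permutation of siRNA labels within vehicle and within R1881 (400 arrangements). A simulated ratio of 0.8 was recovered as 0.796 over 1412 chosen genes. Shared effects of the knockdowns were set against 20 simulations of unchanged groups with the same controls. Sequences of 7 bases in 3' untranslated regions (12827 of 13008 tested protein-coding genes) were tested by a linear model of log2 fold changes on their presence, with linear and squared terms for the region's length and GC content and for expression. A planted effect of -0.2 was ranked first in 20 of 20 simulations that permuted the Nkx2-5 siRNA fold changes in vehicle. Smaller effects, such as the -0.111 reported below, were not simulated. Trends on GC content and transcript length were removed per library as smooth offsets in a repeat of the fit. Sequence counts and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

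Replicates were compared by chi-square of their counts over genes with at least 20 counts. Every pair within a group differed by more than sampling noise (2.37 to 19.0 per degree of freedom), so no library was counted as a repeat. Alternatives were RLE in place of TMM factors, no filter (33046 genes with at least 1 count) and a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, only the groups compared in the fit, a replicate block, a 2-fold minimum, other gene choices for the scores, and each library left out in turn. The use of protein-coding genes alone, and removal of the siRNA mean before permuting scores, were chosen after seeing the data.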

Results

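Gene expression was measured by RNA sequencing in LNCaP cells, an androgen-sensitive human prostate cancer line. Cells were transfected with pools of small interfering RNA (siRNA) against serum response factor (SRF), against the cardiac homeobox factor Nkx2-5, or against no human gene (control). After 42 hours they received vehicle (ethanol) or 5 nM R1881, a synthetic androgen, and RNA was taken 48 hours later. The design gave 6 groups of 3 libraries, which the series describes as biological replicates. The libraries held 13550541 to 22925125 gene counts each, 316994123 in total. In vehicle, the 3 libraries held 22925125, 19222208 and 19288916 counts with control siRNA. They held 18695335, 13550541 and 17147015 with SRF siRNA and 16932932, 15713081 and 17576399 with Nkx2-5 siRNA. In R1881 the totals were 19380289, 18354038 and 18801115 with control siRNA, 16266169, 14232002 and 15132177 with SRF siRNA, and 17294767, 19034069 and 17447945 with Nkx2-5 siRNA. The series asks how far SRF and Nkx2-5 contribute to the androgen response of these cells.

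The siRNA targets were examined before any other gene. SRF (ENSG00000112658.7, chromosome 6, 43171299 to 43181507, plus strand, GRCh38) had 85 to 167 counts in each SRF siRNA library, against 524 to 635 with control siRNA and 459 to 492 with Nkx2-5 siRNA. Its normalised count in vehicle fell from 25.8 ± 0.134 CPM (counts scaled to a common library size; SD, n = 3) with control siRNA to 7.13 ± 1.27 with SRF siRNA. In R1881 it fell from 30.7 ± 1.27 to 7.16 ± 0.765. These are log2 fold changes of -1.84 ± 0.10 (SE; adjusted p = 1.3e-12) and -2.10 ± 0.10 (adjusted p = 1.5e-13) by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. With Nkx2-5 siRNA the SRF level was 26.0 ± 1.45 CPM in vehicle and 28.6 ± 1.13 in R1881. NKX2-5 (ENSG00000183072.9, chromosome 5, 173232109 to 173235357, minus strand) had 0 counts in 17 libraries and 1 count in SRF siRNA R1881 replicate 1. A count of 0 allows up to 0.131 to 0.221 CPM in a library, up to 0.0254 CPM over the 6 control libraries and up to 0.0289 CPM over the 6 Nkx2-5 siRNA libraries. The knockdown of NKX2-5 was therefore not detectable at this depth, in either direction, and these counts do not check the Nkx2-5 siRNA labels.

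On principal components of log2 CPM, the first axis held 65.2% of the variance and separated R1881 from vehicle libraries. The second held 13.3% and mainly set the Nkx2-5 siRNA libraries apart from the others. Scores on it were 32 to 39.97 with Nkx2-5 siRNA, -17.38 to -1.15 with control siRNA and -31.51 to -19.05 with SRF siRNA.

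The makeup of the libraries differed between the siRNA pools in noncoding RNA. Long noncoding genes annotated in the ribosomal RNA region of chromosome 21 took 4.64 ± 1.96% and 4.93 ± 1.20% of counts with SRF siRNA in vehicle and R1881. The shares were 0.887 ± 0.193% and 1.06 ± 0.225% with control siRNA and 1.09 ± 0.159% and 0.958 ± 0.163% with Nkx2-5 siRNA. SRF siRNA vehicle replicate 3 held the most, 6.90%. Mitochondrial ribosomal RNA took 0.213 ± 0.0381% and 0.138 ± 0.00187% of counts with SRF siRNA in vehicle and R1881, and 0.136 to 0.235% in the single libraries. It took 0.0670 ± 0.00734% and 0.0647 ± 0.00518% with Nkx2-5 siRNA and 0.0639 ± 0.00460% with control siRNA in R1881. Control siRNA vehicle replicate 3 held 0.494%, against 0.0465 and 0.0646% in the 2 other libraries of its group. The signal recognition particle RNA RN7SL2 took 5.53 ± 0.506% and 7.07 ± 0.309% in vehicle and R1881 with control siRNA, 7.17 ± 0.674% and 8.47 ± 0.8002% with Nkx2-5 siRNA and 5.26 ± 0.282% and 6.59 ± 0.822% with SRF siRNA. Protein-coding genes took 81.7 to 88.4% of counts.

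**Figure D1:**
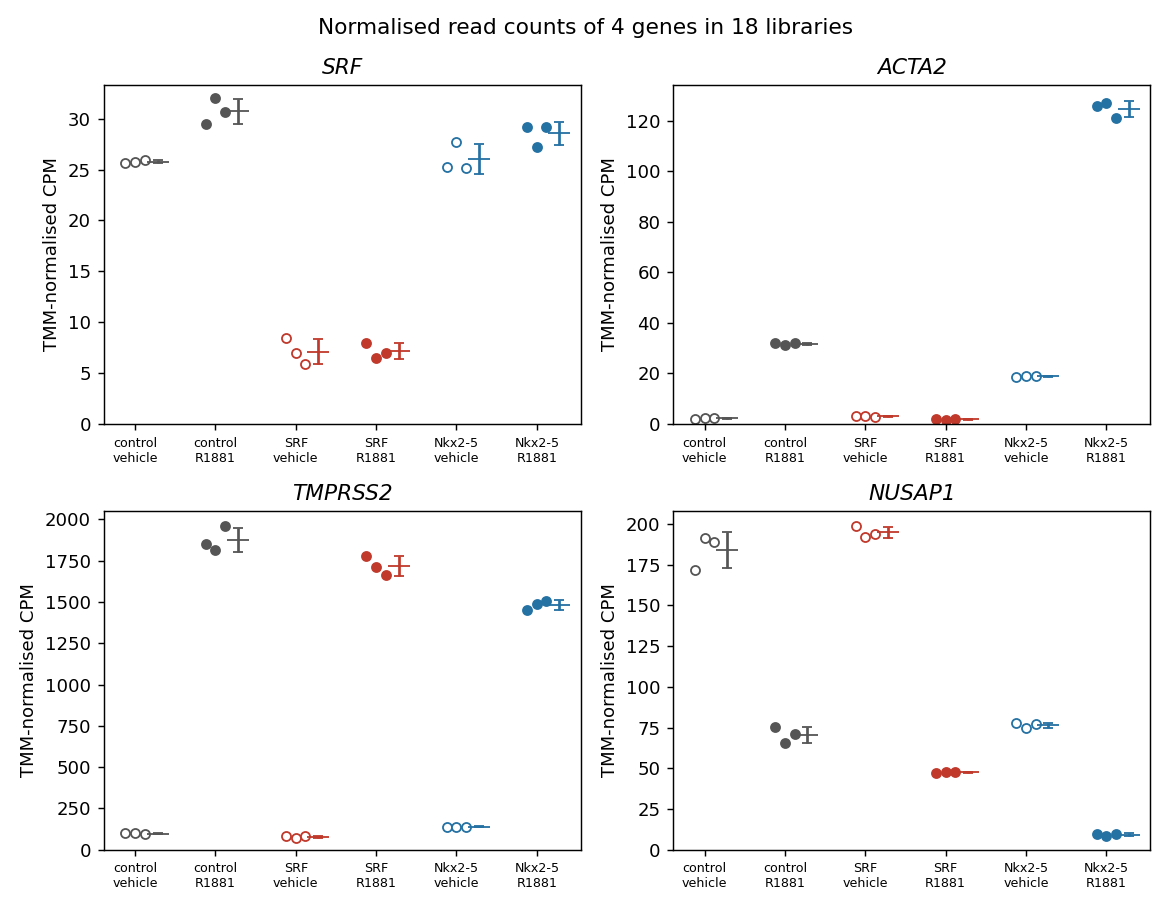
Normalised read counts (TMM-normalised CPM, linear axes from 0) of SRF, ACTA2, TMPRSS2 and NUSAP1 in 18 libraries, with open points for vehicle, filled points for R1881, and the mean ± SD of 3 libraries beside each group. SRF lies near 7 CPM with SRF siRNA, ACTA2 reaches 124.8 CPM with Nkx2-5 siRNA in R1881 and 1.81 CPM with SRF siRNA in R1881, and NUSAP1 falls to 9.29 CPM with Nkx2-5 siRNA in R1881.

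R1881 in control siRNA cells raised the known androgen-induced genes and lowered those of the cell cycle. The transmembrane serine protease gene TMPRSS2 (chromosome 21, 41464551 to 41531116) rose from 97.6 ± 4.15 to 1874 ± 74.6 CPM (n = 3 each), and KLK3, which encodes prostate-specific antigen, from 236.4 ± 12.3 to 5514 ± 217 CPM. Genes are ranked by size, here and for the other comparisons of 2 groups, only among called genes that average at least 50 counts in the higher group and whose groups do not overlap. Among these was the metalloreductase gene STEAP4, with a log2 fold change of 10.67 ± 0.14 (SE), from 0.0816 ± 0.0753 to 135.9 ± 2.70 CPM. Large rises were also measured for CCDC141 (8.68 ± 0.20) and ANGPT2, an angiopoietin (8.19 ± 0.18). The glucose transporter gene SLC2A3 went from 1 count over the 3 vehicle libraries to 1045, a ratio per total count of 1136 (95% counting interval 203.4 to 44900). The keratin gene KRT6B went from 2 to 1481 counts (ratio 804.7, 222.4 to 6651) and the signalling adaptor gene TRAF1 from 1 to 419 (ratio 455.3, 81.3 to 18030). The noncoding RNA PCAT18 and the elastase gene MMP12 had 0 counts in vehicle and were at least 70.6-fold and 62.7-fold higher in R1881, against a floor of 3 counts over the group. These intervals and floors cover counting error only.

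Large falls with R1881 in control siRNA cells were those of the kappa opioid receptor gene OPRK1 (log2 fold change -4.62 ± 0.13, 48.5 ± 1.98 to 1.96 ± 0.615 CPM), the adhesion gene AMIGO2 (-5.18 ± 0.27) and CNBD1 (-5.14 ± 0.30). KCNU1, a potassium channel gene (-5.09 ± 0.33), the metalloprotease gene TLL1 (-4.78 ± 0.20), the disaccharidase gene SI (-4.58 ± 0.18) and the decarboxylase gene DDC (-4.56 ± 0.15) followed. The noncoding RNA LINC01326 went from 150 counts to 1 (ratio 138, 24.4 to 5488). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 10314 of 16690 genes at adjusted p under 0.05. Of these, 5134 were higher and 5180 lower, and 2787 changed at least 2-fold. Each gene named here by its size had an adjusted p of at most 2.75e-09. For these genes, and those named by size for the other comparisons of 2 groups, all 3 libraries of a group lay above all 3 of the other, an order that 10% of random splits give for any gene.

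All 30 listed androgen-induced genes rose with R1881 in control siRNA cells, and 30 rose when adjusted over the list alone (camera adjusted p = 9.51e-142 with a preset correlation, 2.69e-07 with an estimated correlation). Examples were TMPRSS2 (4.26 ± 0.05), the immunophilin gene FKBP5 (4.56 ± 0.07) and STEAP4. All 9 measured androgen-repressed genes fell, 9 adjusted over the list alone (adjusted p = 0.000142 with an estimated correlation), among them UGT2B15 (-4.38 ± 0.11) of steroid glucuronidation, CAMK2N1 (-3.43 ± 0.09) and OPRK1. The 20 cholesterol synthesis genes all rose, 20 over the list alone (adjusted p = 0.000619 with an estimated correlation), with HMGCS1 at 2.61 ± 0.05 and INSIG1, a regulator of that pathway, at 2.30 ± 0.05. Of 13 fatty acid synthesis genes 11 rose and 1 fell, the same numbers over the list alone (adjusted p = 0.000135 with an estimated correlation). Examples are the elongases ELOVL7 (3.72 ± 0.07) and ELOVL5 (2.78 ± 0.05) and the desaturase FADS1 (1.62 ± 0.04).

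Cell division genes moved the other way. Of 22 DNA replication genes 22 fell, 22 over the list alone (adjusted p = 3e-05 with an estimated correlation). Among them were the helicase subunits MCM4 (-1.19 ± 0.05) and MCM2 (-1.37 ± 0.05) and the methylation regulator UHRF1 (-1.496 ± 0.06). All 22 mitosis genes fell, 22 over the list alone (adjusted p = 0.00106 with an estimated correlation). The cyclin-dependent kinase CDK1 lay at -1.44 ± 0.05, CCNB2 at -1.58 ± 0.06 and the spindle protein gene NUSAP1 at -1.38 ± 0.05. Of 21 tested actin cytoskeleton genes bound by SRF with its cofactor MRTF, 16 rose and 2 fell, as over the list alone (adjusted p = 0.00173 with an estimated correlation). The smooth muscle actin gene ACTA2 rose from 2.33 ± 0.170 to 31.8 ± 0.401 CPM (3.78 ± 0.08), the tropomyosin gene TPM1 by 1.58 ± 0.04 and WDR1, an actin disassembly factor, by 1.02 ± 0.04. The smooth muscle actin ACTG2 had 0 counts in vehicle and was at least 26.4-fold higher in R1881.

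Stress and signalling lists were measured with R1881 in control siRNA cells too. Of 20 unfolded protein response genes 18 rose and 0 fell, as over the list alone (adjusted p = 0.00634 with an estimated correlation), including CREB3L4 (1.34 ± 0.05), HERPUD1 (1.18 ± 0.04) and DNAJC3 (1.07 ± 0.05). Of 17 p53 target genes 13 fell and 3 rose, as over the list alone (adjusted p = 0.0386 with an estimated correlation). The sestrin gene SESN1 (-2.05 ± 0.06) and TP53INP1 (-1.64 ± 0.07) fell, and GDF15, a secreted stress factor, rose (2.54 ± 0.07). Of 19 interferon response genes 11 rose and 2 fell, as over the list alone, led by the chemokine gene CXCL10 (5.42 ± 0.18), with adjusted p = 0.048 at the preset and 0.414 with an estimated correlation. Of 7 tested immediate early genes, bound by SRF with the TCF cofactors, 3 rose and 1 fell, as over the list alone (adjusted p = 0.044, and 0.105 with an estimated correlation), with ATF3 at 2.44 ± 0.06 and NR4A1 at 1.45 ± 0.12. Of 26 ribosomal protein genes 24 fell, 24 over the list alone, by small amounts such as RPS2 (-0.48 ± 0.05) and RPS19 (-0.47 ± 0.05), with adjusted p = 0.00414 at the preset and 0.579 with an estimated correlation. Of 13 mitochondrially encoded transcripts 9 rose, 9 over the list alone (adjusted p = 0.37), for example MT-CO2 (0.39 ± 0.06).

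Among marker lists in control siRNA cells, 6 of 11 luminal epithelial markers rose and 5 fell with R1881, as over the list alone (adjusted p = 0.0199 with an estimated correlation). The keratins KRT8 (2.31 ± 0.05), KRT18 (1.90 ± 0.05) and KRT19 (3.93 ± 0.13) were higher. Of 5 tested basal markers 4 rose and 1 fell (adjusted p = 0.13), among them the laminin gene LAMB3 (3.59 ± 0.20). Of 3 tested neuroendocrine markers 1 rose and 2 fell, of 7 fibroblast and smooth muscle markers 3 rose and 4 fell, of 5 leukocyte markers 4 rose and 1 fell, and of 5 tested cardiac genes regulated by NKX2-5 3 rose and 0 fell. Counts over the list alone were the same for each of these marker and cardiac lists, and none of the last 4 passed camera (adjusted p = 0.13, 0.94, 0.63 and 0.76).

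With SRF siRNA, R1881 raised 5368 and lowered 5322 genes, 10690 in all by the same edgeR quasi-likelihood test. The acute-phase protein genes ORM1 and ORM2 went from 1 count each over the vehicle libraries to 1489 and 1247, ratios of 1612 (288.8 to 63700) and 1350 (241.8 to 53360). SLC2A3 went from 1 to 1223 counts (ratio 1324, 237.2 to 52330) and the amino acid transporter gene SLC38A4 from 2 to 771 (ratio 417.3, 115.1 to 3452). STEAP4 rose by 9.24 ± 0.13 on the log2 scale and the tubulin gene TUBA3D by 8.64 ± 0.19. The glucose transporter gene SLC2A10 and the protease gene CTSE had 0 vehicle counts and were at least 64.95-fold and 63.9-fold higher. Large falls were those of the glucagon gene GCG, COL3A1, a fibrillar collagen (-5.60 ± 0.40), DDC (-5.45 ± 0.18), SI (-5.28 ± 0.16), the synaptic protein gene CBLN2 (-5.25 ± 0.15) and SLITRK3 (-5.18 ± 0.32). CNBD1 fell from 194 counts to 3 (ratio 59.7, 20.1 to 292.2) and the potassium channel gene KCNJ3 from 160 to 3 (ratio 49.3, 16.6 to 241.4). Each had an adjusted p of at most 4.52e-08 (edgeR quasi-likelihood, Benjamini-Hochberg).

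In these SRF siRNA cells 30 of 30 androgen-induced genes rose with R1881 (30 over the list alone, adjusted p = 6.35e-07 with an estimated correlation), with TMPRSS2 at 4.43 ± 0.06 and the transcription factor gene MAF at 6.68 ± 0.09. All 9 androgen-repressed genes fell (9 over the list alone, adjusted p = 0.000786 with an estimated correlation), including UGT2B15 (-4.09 ± 0.11) and CAMK2N1 (-3.11 ± 0.09). All 22 mitosis and all 22 replication genes fell, as over the lists alone (adjusted p = 0.000329 and 9.0e-06 with an estimated correlation), with NUSAP1 at -2.04 ± 0.06, BUB1B, a spindle checkpoint kinase, at -2.25 ± 0.07 and MCM4 at -1.58 ± 0.05. Cholesterol synthesis genes rose in 20 of 20 cases (20 over the list alone, adjusted p = 0.00106 with an estimated correlation), HMGCS1 by 2.84 ± 0.06. Of the 21 actin genes 12 rose and 5 fell (13 and 6 over the list alone), with adjusted p = 0.044 at the preset and 0.127 with an estimated correlation. TPM1 rose by 1.70 ± 0.04 and WDR1 by 0.96 ± 0.04, while ACTA2 fell by 0.78 on the log2 scale, to 1.81 ± 0.124 CPM. Interferon genes rose in 16 of 19 cases and fell in 1, as over the list alone, with CXCL10 at 5.86 ± 0.14 (adjusted p = 0.000121, and 0.124 with an estimated correlation).

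With Nkx2-5 siRNA, R1881 raised 5148 and lowered 5427 genes, 10575 in all. STEAP4 rose by 9.96 ± 0.13 on the log2 scale, CCDC141 by 8.27 ± 0.19, the pepsinogen gene PGC by 8.09 ± 0.15 and SLC2A3 by 8.31 ± 0.21. KRT6B went from 3 to 779 counts (ratio 242.5, 82.7 to 1178). The pseudogene UGT2B24P, the acute-phase gene SAA1 and the noncoding RNA PCA3 had 0 counts in vehicle and were at least 83.1-fold, 68.2-fold and 50.7-fold higher. CYP7A1, the rate-limiting enzyme of bile acid synthesis, fell by 6.51 ± 0.29 on the log2 scale. The phospholipase gene PLD1 (-5.50 ± 0.37), the chemokine receptor gene ACKR3 (-5.15 ± 0.16), the cholinesterase gene BCHE (-5.09 ± 0.20), SLITRK3 (-5.79 ± 0.44), SI (-4.95 ± 0.20) and CBLN2 (-4.90 ± 0.30) also fell, and AMIGO2 went from 197 counts to 3 (ratio 70.3, 23.7 to 343.9). Each adjusted p was at most 2.78e-10 (edgeR quasi-likelihood, Benjamini-Hochberg).

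In the Nkx2-5 siRNA cells 30 of 30 androgen-induced genes rose with R1881 (30 over the list alone, adjusted p = 6.35e-07 with an estimated correlation), FKBP5 by 5.11 ± 0.07 and the centromere protein gene CENPN by 3.69 ± 0.05. Of 9 androgen-repressed genes 8 fell (8 over the list alone, adjusted p = 0.000759 with an estimated correlation), CAMK2N1 at -4.45 ± 0.11. All 22 mitosis and all 22 replication genes fell, as over the lists alone (adjusted p = 0.000207 and 4.35e-05 with an estimated correlation), with NUSAP1 at -3.04 ± 0.07, the kinesin gene KIF20A at -2.64 ± 0.07 and MCM7 at -2.02 ± 0.06. Actin genes rose in 16 of 21 cases and fell in 3, as over the list alone (adjusted p = 0.000759 with an estimated correlation), ACTA2 by 2.73 ± 0.05. All 20 cholesterol synthesis genes rose, 20 over the list alone (adjusted p = 0.000548 with an estimated correlation), HMGCS1 by 3.69 ± 0.06. Of 17 p53 targets 14 fell and 2 rose, as over the list alone (adjusted p = 0.0109 with an estimated correlation), with GDF15 at 2.85 ± 0.07 and TP53INP1 at -2.32 ± 0.07. Across the 16690 genes, R1881 log2 fold changes of the control arm correlated with those of the SRF arm at r = 0.903 (rho = 0.868) and of the Nkx2-5 arm at r = 0.873 (rho = 0.817). In both arms of these pairs, 8723 and 8077 genes were called in the same direction and 40 and 251 in opposite directions. Genes are not independent replicates, so no p is attached to these correlations.

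**Figure D2:**
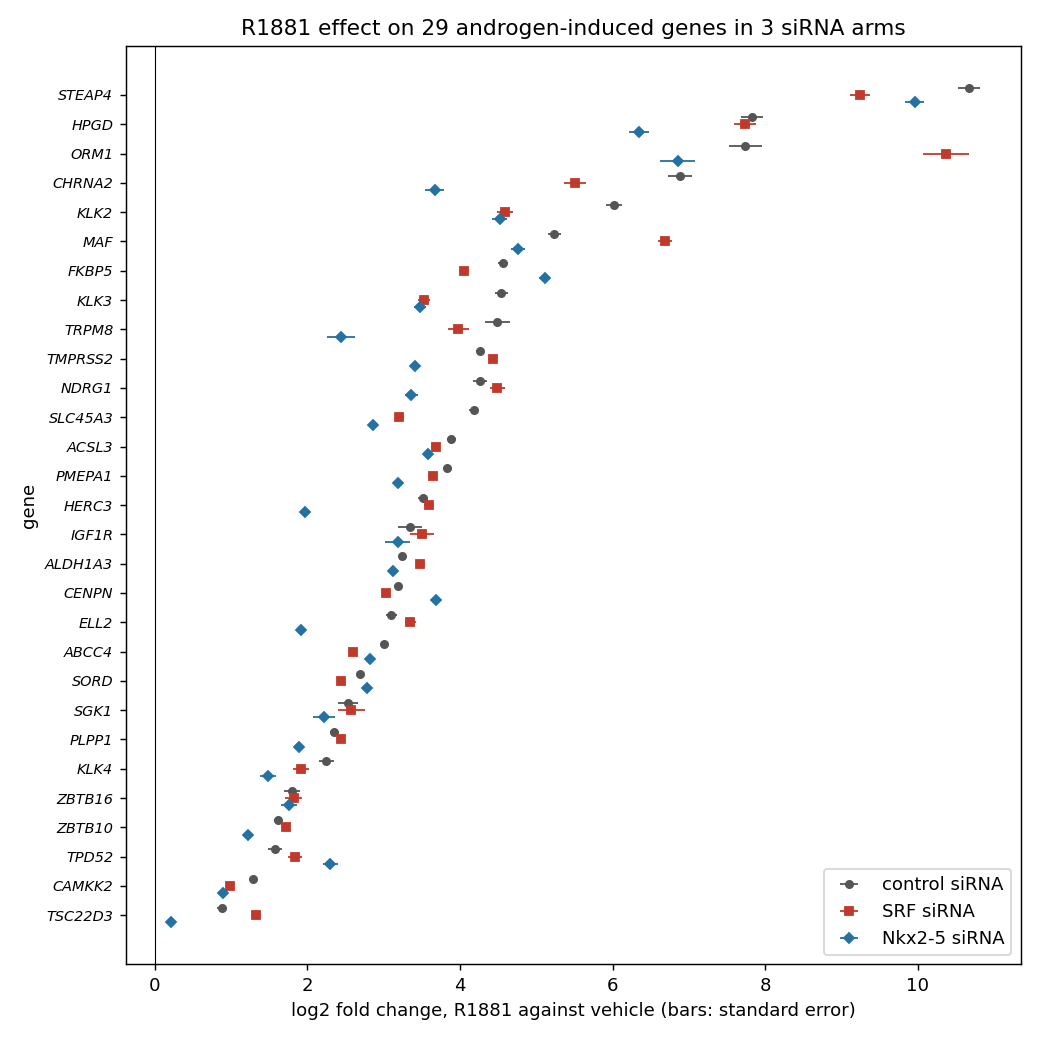
R1881 effect on 29 of the 30 androgen-induced genes, as log2 fold change against vehicle (horizontal axis, bars are standard errors) in control, SRF and Nkx2-5 siRNA cells (3 libraries per group). All 87 points lie above 0, and in the Nkx2-5 arm HERC3 and ELL2 lie left of both other arms.

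SRF siRNA in vehicle lowered SRF itself and part of the actin cytoskeleton genes, and raised interferon response genes. Besides SRF, the largest ranked falls were those of the amine oxidase gene AOC1 (log2 fold change -3.89 ± 0.30), the interferon-induced GTPase gene GBP2 (-3.30 ± 0.28), the exchange factor gene VAV3 (-1.83 ± 0.18), BVES (-1.44 ± 0.15), the ubiquitin-like modifier gene SUMO3 (-1.39 ± 0.05, 115.5 ± 2.68 to 44.1 ± 0.878 CPM), the RNA-binding protein gene RBM24 (-1.39 ± 0.13) and TMEM140 (-1.35 ± 0.09). KCNJ3 (2.94 ± 0.35), ADAM7 (2.06 ± 0.14), the growth factor gene IGF1 (1.96 ± 0.25), the ERK phosphatase gene DUSP5 (1.77 ± 0.12), FGL1 (1.76 ± 0.25), LRRC4C (1.74 ± 0.23), ZNF703 (1.66 ± 0.16) and CBLN2 (1.64 ± 0.10) had the largest rises among genes with at least 50 counts. The edgeR quasi-likelihood test called 4670 genes, 2243 higher and 2427 lower, of which 348 changed at least 2-fold. Each named gene had an adjusted p of at most 1.42e-05 (Benjamini-Hochberg). Without the filter on low counts, which also changes the scaling and gives each gene the general trend's spread in place of its own, 1700 of 4680 called genes were higher (36.3%), against 2243 of 4670.

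Of the 21 actin genes 8 fell and 2 rose with SRF siRNA in vehicle (9 and 3 over the list alone, adjusted p = 0.0187 with an estimated correlation). The cytoplasmic actin gene ACTB fell from 1216 ± 22.8 to 735.9 ± 18.8 CPM (-0.72 ± 0.04), and the actin-binding protein genes CALD1 (-0.77 ± 0.05) and CNN2 (-0.66 ± 0.10) fell too. Interferon response genes rose in 14 of 19 cases and fell in 1 (14 and 2 over the list alone, adjusted p = 0.0221 with an estimated correlation), with IFI6 at 1.21 ± 0.10, IFIT1 at 1.002 ± 0.11 and IFI27 at 1.92 ± 0.24. All 13 mitochondrially encoded transcripts rose, 13 over the list alone, such as MT-ND1 (0.98 ± 0.14) and MT-ND5 (0.74 ± 0.12). The camera adjusted p was 4.2e-09 at the preset and 0.12 with an estimated correlation. These libraries held 4.64 ± 1.96% ribosomal RNA region and 0.213 ± 0.0381% mitochondrial ribosomal RNA counts. Of 7 immediate early genes 3 rose and 1 fell, as over the list alone (adjusted p = 0.26), EGR1 by 3.47 ± 0.56 and MCL1 at -0.38 ± 0.05. Androgen-induced genes split into 11 higher and 7 lower of 30 (12 and 7 over the list alone, adjusted p = 0.0805), with SLC45A3 at 1.02 ± 0.06 above the lipid phosphatase gene PLPP1 at -0.57 ± 0.05. Of 22 replication genes 4 rose and 2 fell (6 and 2 over the list alone, adjusted p = 0.3), numbers that turned to 1 and 2 without the low-count filter. Of 22 mitosis genes 5 rose (3 over the list alone, adjusted p = 0.071), 2 rose and 1 fell without that filter, and 1 rose without control siRNA vehicle replicate 3 or without SRF siRNA vehicle replicate 3, the latter with 1 lower.

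In R1881, SRF siRNA lowered part of the actin cytoskeleton genes. ACTA2 (chromosome 10, 88935074 to 88991339, minus strand) fell from 31.8 ± 0.401 to 1.81 ± 0.124 CPM (n = 3 each), a log2 fold change of -4.13 ± 0.09, and the myosin light chain gene MYL9 from 2.87 ± 0.0778 to 0.1435 ± 0.125 CPM (-4.28 ± 0.41). ACTG2 and the atrial light chain gene MYL7 had 0 counts with SRF siRNA and were at least 19.6-fold and 9.69-fold lower. GBP2 (-2.98 ± 0.16), SRF, the insulin-responsive glucose transporter gene SLC2A4 (-1.971 ± 0.15), the antisense RNAs MBNL1-AS1 (-1.94 ± 0.24) and MCPH1-AS1 (-1.92 ± 0.22), and C8orf4 (-1.87 ± 0.16) also fell. The antiviral synthetase gene OAS2 (2.42 ± 0.20), the myosin-binding protein gene MYBPC1 (2.32 ± 0.07), CTSE (2.12 ± 0.24), ALDH3B2 (2.04 ± 0.07), CXCL10 (1.98 ± 0.09), SPRY4, a feedback inhibitor of ERK signalling (1.87 ± 0.12), BCAS1 (1.78 ± 0.12) and ATP10D (1.77 ± 0.24) had the largest rises among genes with at least 50 counts. In all, 4629 genes were called, 2232 higher and 2397 lower, with adjusted p of at most 6.35e-06 for each gene named by size (edgeR quasi-likelihood, Benjamini-Hochberg). Strand was not stated for the counting, so reads of an antisense RNA and its partner cannot be told apart.

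Of the 21 actin genes 12 fell and 1 rose with SRF siRNA in R1881 (13 and 2 over the list alone, adjusted p = 9.0e-06 with an estimated correlation), including ACTB (-0.93 ± 0.04), TPM4 (-0.91 ± 0.05) and the filamin gene FLNA (-1.22 ± 0.08). Interferon genes rose in 16 of 19 cases and fell in 0 (16 and 1 over the list alone, adjusted p = 0.000274 with an estimated correlation), with IFI6 at 1.67 ± 0.10 and IFIT1 at 1.55 ± 0.10. Of 22 mitosis genes 21 fell, 21 over the list alone (adjusted p = 0.0109 with an estimated correlation), NUSAP1 at -0.57 ± 0.06 and the kinetochore gene NDC80 at -0.65 ± 0.07. Of 22 replication genes 18 fell, 19 over the list alone (adjusted p = 0.000376 with an estimated correlation), GINS1 at -0.78 ± 0.07 and the ribonucleotide reductase gene RRM2 at -0.74 ± 0.08. All 7 immediate early genes passed the test, 4 higher and 3 lower, as over the list alone (adjusted p = 0.93), with JUNB at 0.61 ± 0.08 and MCL1 at -0.45 ± 0.05. Androgen-induced genes were higher in 7 and lower in 13 of 30 cases (8 and 13 over the list alone, adjusted p = 0.6), with the kallikrein gene KLK2 at -0.86 ± 0.08. Unfolded protein response genes fell in 8 of 20 cases and rose in 2 (9 and 3 over the list alone), ATF4 at -0.56 ± 0.05, with adjusted p = 0.00151 at the preset and 0.124 with an estimated correlation.

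Nkx2-5 siRNA in vehicle raised the cell cycle inhibitor gene CDKN1A (p21; chromosome 6, 36676460 to 36687339) from 183 ± 12.8 to 1160 ± 6.05 CPM (n = 3 each), a log2 fold change of 2.66 ± 0.05, and lowered nearly all listed cell division genes. Among genes with at least 50 counts, CYP7A1 had the largest rise (4.31 ± 0.21, 0.472 ± 0.128 to 9.47 ± 0.497 CPM), followed by the interferon-induced gene IFI27 (3.13 ± 0.20), the neuropeptide gene CARTPT (3.12 ± 0.28), SPRY4 (3.06 ± 0.20), ACTA2 (3.02 ± 0.08), LDLRAD1 (2.84 ± 0.24) and MEGF10 (2.42 ± 0.26). TLL1 (-2.82 ± 0.15), the bile salt export pump gene ABCB11 (-2.81 ± 0.27), the glucan receptor gene CLEC7A (-2.41 ± 0.22), SLITRK6 (-2.39 ± 0.15), the ephrin receptor gene EPHA7 (-2.31 ± 0.11), AOC1 (-2.27 ± 0.23), TMEFF2 (-2.18 ± 0.08) and CCDC80 (-2.03 ± 0.22) had the largest falls among them. The edgeR quasi-likelihood test called 7234 genes, 3578 higher and 3656 lower, 843 of them at least 2-fold, with adjusted p of at most 5.5e-08 for each gene named by size (Benjamini-Hochberg). Genes whose 3' untranslated region held the sequence AGAGCAA were called lower in 36.9% and higher in 16.0% of cases, against 23.5% and 26.0% of genes without it. These shares are not adjusted for the region's length, its GC content or expression.

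Of 22 mitosis genes 22 fell with Nkx2-5 siRNA in vehicle, 22 over the list alone (adjusted p = 7.0e-05 with an estimated correlation), NUSAP1 from 184.1 ± 10.98 to 76.4 ± 1.49 CPM (-1.27 ± 0.05), CDK1 at -1.18 ± 0.05 and KIF20A at -1.12 ± 0.05. Of 22 replication genes 21 fell, 21 over the list alone (adjusted p = 1.6e-06 with an estimated correlation), UHRF1 at -1.53 ± 0.06, MCM3 at -1.01 ± 0.05 and the licensing factor gene CDC6 at -1.03 ± 0.05. Of 17 p53 targets 14 rose and 1 fell, as over the list alone (adjusted p = 0.000258 with an estimated correlation), with CDKN1A, TP53I3 (1.44 ± 0.11) and the mitochondrial reductase gene FDXR (0.99 ± 0.08) as examples. Interferon response genes rose in 14 of 19 cases and fell in 4, as over the list alone (adjusted p = 0.0189 with an estimated correlation), with the ubiquitin-like gene ISG15 at 1.67 ± 0.07 and IFI6 at 2.16 ± 0.09. Actin genes rose in 12 of 21 cases and fell in 2, as over the list alone (adjusted p = 0.00796 with an estimated correlation), with ACTA2, TPM1 (0.52 ± 0.04) and MYL9 (4.82 ± 0.42) higher and TPM4 lower (-0.47 ± 0.05). ACTG2 had 0 counts with control siRNA and was at least 21.6-fold higher. Of 9 androgen-repressed genes 6 fell and 1 rose (7 and 1 over the list alone, adjusted p = 0.0136 with an estimated correlation), OPRK1 at -1.83 ± 0.09 and UGT2B15 at -1.74 ± 0.09. Androgen-induced genes rose in 14 and fell in 9 of 30 cases (15 and 10 over the list alone), with the ubiquitin ligase gene HERC3 at 1.499 ± 0.06 and FKBP5 at -1.002 ± 0.07 (adjusted p = 0.0215, and 0.21 with an estimated correlation). Of 5 cardiac genes regulated by NKX2-5 2 rose (2, with 1 lower, over the list alone; adjusted p = 0.33), among them MYL7, from 1 to 88 counts (ratio 107.6, 18.8 to 4300). Mitochondrial transcripts rose in 8 of 13 cases (10 over the list alone), with MT-CO2 at 0.52 ± 0.06 (adjusted p = 0.00255, and 0.4 with an estimated correlation).

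In R1881, the 8 largest ranked falls with Nkx2-5 siRNA were those of the spindle gene CKAP2L (-3.41 ± 0.21), the replication initiation gene MCM10 (-3.33 ± 0.11, 23.4 ± 0.220 to 2.33 ± 0.676 CPM), the condensin gene NCAPG (-3.19 ± 0.09), the kinesin gene KIF18B (-3.18 ± 0.25), the mitotic kinase gene PBK (-3.17 ± 0.14), the cytokinesis gene CEP55 (-3.12 ± 0.12), the centromeric histone gene CENPA (-3.08 ± 0.23) and the kinetochore gene SPC25 (-3.07 ± 0.28). The stromelysin gene MMP10 (chromosome 11, 102770503 to 102780628) rose from 0.373 ± 0.132 to 11.4 ± 0.846 CPM (4.89 ± 0.24), ahead, among ranked genes, of MYL7 (3.83 ± 0.29), MMP12 (3.75 ± 0.12), MCPH1-AS1 (3.61 ± 0.12), SAA1 (3.55 ± 0.31), the skeletal actin gene ACTA1 (3.43 ± 0.32), the thyroid hormone deiodinase gene DIO3 (3.10 ± 0.18) and IFI27 (2.80 ± 0.15). In all, 7679 genes were called, 3594 higher and 4085 lower (46.8% higher, and 51.5% on protein-coding genes alone), 1156 of them at least 2-fold, with adjusted p of at most 2.89e-08 for each gene named by size (edgeR quasi-likelihood, Benjamini-Hochberg). Genes with AGAGCAA in the 3' untranslated region were called lower in 37.4% and higher in 19.96% of cases, against 26.0% and 25.8% without it, again with no adjustment for length, GC content or expression.

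All 22 mitosis genes fell with Nkx2-5 siRNA in R1881, 22 over the list alone (adjusted p = 9.0e-06 with an estimated correlation), with NUSAP1 at -2.93 ± 0.07, CDK1 at -2.12 ± 0.06 and KIF20A at -2.55 ± 0.07. Of 22 replication genes 21 fell, 22 over the list alone (adjusted p = 1.9e-06 with an estimated correlation), RRM2 at -3.03 ± 0.09. Androgen-induced genes fell in 22 of 30 cases and rose in 4, as over the list alone (adjusted p = 0.0154 with an estimated correlation), PLPP1 at -0.97 ± 0.05 and the kinase gene CAMKK2 at -0.68 ± 0.05. Interferon genes rose in 17 of 19 cases and fell in 1 (18 and 1 over the list alone, adjusted p = 0.00165 with an estimated correlation), with ISG15 at 1.76 ± 0.07 and IFI6 at 2.33 ± 0.10. Actin genes rose in 11 of 21 cases and fell in 2 (13 and 2 over the list alone, adjusted p = 0.00132 with an estimated correlation), with ACTA2 at 1.971 ± 0.05 and TPM1 at 0.66 ± 0.04. Of 17 p53 targets 9 rose and 1 fell, as over the list alone (adjusted p = 0.00655 with an estimated correlation), with CDKN1A at 2.11 ± 0.05 and GDF15 at 0.93 ± 0.07. Basal markers rose in 4 of 5 cases and fell in 1, as over the list alone (adjusted p = 0.0485 with an estimated correlation), with LAMB3 at 1.44 ± 0.12 and KRT15 at 2.04 ± 0.19. Unfolded protein response genes fell in 12 of 20 cases and rose in 4 (13 and 4 over the list alone), with PDIA4 at -0.90 ± 0.04 and TRIB3 at 0.84 ± 0.05 (adjusted p = 0.00831, and 0.193 with an estimated correlation). Cholesterol synthesis genes rose in 10 of 20 cases and fell in 1, as over the list alone, with HMGCS1 at 1.11 ± 0.05 (adjusted p = 6.5e-05, and 0.159 with an estimated correlation).

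**Figure D3:**
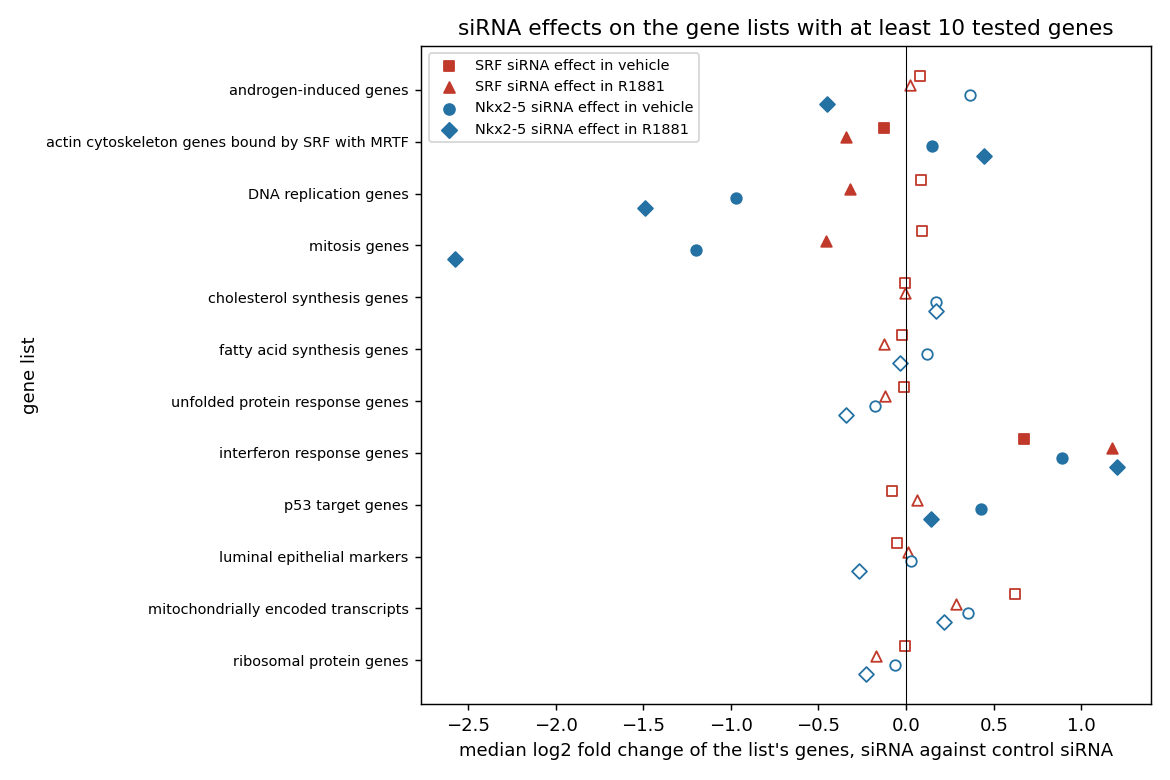
Median log2 fold change of the genes of each list with at least 10 tested genes (horizontal axis), for SRF and Nkx2-5 siRNA against control siRNA in vehicle and in R1881. Filled symbols passed camera with an estimated correlation, and the mitosis list has medians of -1.20 and -2.58 with Nkx2-5 siRNA and 0.09 and -0.46 with SRF siRNA in vehicle and R1881.

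Whether the R1881 effect itself differed with SRF siRNA was tested as an interaction, which called 1457 of 16690 genes, 725 with a higher and 732 with a lower R1881 effect than with control siRNA (edgeR quasi-likelihood, adjusted p under 0.05 by Benjamini-Hochberg). Higher and lower effects, here and for the other differences, refer to the signed log2 value. A lower effect is a smaller rise for a gene that R1881 raised, and a deeper fall for a gene that it lowered. R1881 raised ACTA2 13.7-fold with control siRNA, and the difference with SRF siRNA was -4.56 ± 0.15 on the log2 scale. Of 21 actin genes 5 had a lower and 1 a higher effect, as over the list alone (adjusted p = 0.00124 with an estimated correlation), with TPM4 at -0.86 ± 0.07 and FLNA at -0.75 ± 0.11. Cell division genes had a lower R1881 effect in 21 of 22 mitosis genes (22 over the list alone) and 18 of 22 replication genes (20 over the list alone), with adjusted p = 0.000759 and 3.0e-05 with an estimated correlation. R1881 lowered these genes in both arms, so their falls were deeper with SRF siRNA. NUSAP1 (-0.65 ± 0.08), CENPF (-0.79 ± 0.10), BUB1B (-0.69 ± 0.09), CDC6 (-0.52 ± 0.07), RRM2 (-0.67 ± 0.10) and MCM10 (-0.63 ± 0.10) were examples. Other lower effects were those of MCPH1-AS1 (-3.34 ± 0.50), IGF1 (-2.37 ± 0.41), C8orf4 (-2.33 ± 0.40) and RN7SL838P (-2.25 ± 0.55). Higher effects were measured for the transcription factor gene SOX9 (1.77 ± 0.27), VAV3 (1.75 ± 0.37), the adrenergic receptor gene ADRA2A (1.65 ± 0.18), ATP10D (1.61 ± 0.35), SUSD2 (1.47 ± 0.34) and MAF (1.45 ± 0.14). Of 30 androgen-induced genes 9 had a lower and 2 a higher effect (10 and 6 over the list alone), with adjusted p = 0.000762 at the preset and 0.0838 with an estimated correlation, and 7 a higher effect without the low-count filter. The balance of directions depended on the setting. Without that filter 1129 of 1733 called genes were higher (65.2%, against 49.8%), on protein-coding genes alone, a setting chosen after the data were seen, 636 of 1494 (42.6%), and without SRF siRNA R1881 replicate 2 or 3 the share was 60.2% and 61.0%.

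The R1881 effect differed in more genes with Nkx2-5 siRNA, where 3584 were called, 1435 with a higher and 2149 with a lower effect than with control siRNA (edgeR quasi-likelihood, adjusted p under 0.05 by Benjamini-Hochberg). The share with a higher effect was 40.0%, against 47.5% (1626 of 3425) on protein-coding genes alone and 47.2% (1578 of 3344) without the low-count filter. Of 30 androgen-induced genes 20 had a lower and 3 a higher effect, as over the list alone (adjusted p = 0.000376 with an estimated correlation). HERC3 rose from 39.1 ± 2.56 to 447.5 ± 14.3 CPM with control siRNA and from 110.7 ± 1.91 to 433.2 ± 9.004 CPM with Nkx2-5 siRNA, a difference of -1.55 ± 0.08. SLC45A3 (-1.32 ± 0.08) and the nicotinic receptor gene CHRNA2 (-3.21 ± 0.27) had lower effects too. All 22 mitosis genes (22 over the list alone) and 14 of 22 replication genes (15 over the list alone) had a lower effect, none a higher one, with adjusted p = 9.9e-05 and 0.00011 with an estimated correlation. R1881 lowered these genes in both arms, so their falls were deeper with Nkx2-5 siRNA. NUSAP1 (-1.66 ± 0.09), KIF20A (-1.43 ± 0.09), BUB1B (-1.72 ± 0.11), MCM10 (-2.23 ± 0.14), RRM2 (-1.84 ± 0.12) and MCM7 (-0.88 ± 0.08) were examples. SPRY4 (-3.21 ± 0.26), MYL9 (-2.88 ± 0.53), the coagulation factor gene F5 (-2.85 ± 0.45) and MOGAT2 (-2.60 ± 0.50) also had lower effects. Higher effects were those of AOC1 (3.64 ± 0.46), the protease genes MMP7 (3.35 ± 0.51) and MMP10 (2.90 ± 0.49), VSTM2L (2.68 ± 0.28), ARHGAP20 (2.58 ± 0.29), the immune regulator gene NLRC5 (2.53 ± 0.21) and the death-associated kinase gene DAPK1 (2.45 ± 0.27).

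Between the SRF and Nkx2-5 arms, with no control library, 4193 genes differed in their R1881 effect, 2566 higher and 1627 lower with SRF siRNA (61.2% higher, against 50.3%, 2016 of 4012, on protein-coding genes alone). Of 100 groupings of these 12 libraries, the real one included, 5 gave as many called genes. Groupings that mix the arms carry the average siRNA effect. Androgen-induced genes had a higher effect with SRF siRNA in 17 of 30 cases and a lower one in 5, as over the list alone (adjusted p = 0.00691 with an estimated correlation), with HERC3 at 1.62 ± 0.08, ELL2, an elongation factor, at 1.44 ± 0.10 and TMPRSS2 at 1.01 ± 0.07. Mitosis genes were higher in 19 of 22 cases, 19 over the list alone (adjusted p = 0.0086 with an estimated correlation), with KIF20A at 1.02 ± 0.09, NUSAP1 at 1.01 ± 0.09 and CDC20 at 1.29 ± 0.14. R1881 lowered these 19 genes less with SRF than with Nkx2-5 siRNA. Actin genes were lower in 8 and higher in 2 of 21 cases (8 and 3 over the list alone, adjusted p = 0.00421 with an estimated correlation), with ACTA2 at -3.51 ± 0.14, TPM4 at -1.43 ± 0.07 and FLNA at -1.56 ± 0.11. Of 17 p53 targets 7 were higher and 2 lower (8 and 3 over the list alone, adjusted p = 0.048 with an estimated correlation), with CDKN1A at 0.72 ± 0.07. CARTPT (4.26 ± 0.61), SPRY4 (3.29 ± 0.21), MOGAT2 (3.28 ± 0.51), TUBA3D (3.09 ± 0.45), SERPIND1 (3.03 ± 0.59), the defensin gene DEFB132 (2.26 ± 0.16) and TENM1 (2.25 ± 0.34) were among the genes with higher effects. MCPH1-AS1 (-5.39 ± 0.47), MMP10 (-5.10 ± 0.38), GLIPR1 (-3.66 ± 0.69), C8orf4 (-3.63 ± 0.42) and the glucuronosyltransferase gene UGT2B11 (-3.52 ± 0.12) were among those with lower ones. Each gene named by size here had an adjusted p of at most 0.000391 (edgeR quasi-likelihood, Benjamini-Hochberg).

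The size of the androgen response was compared over large gene sets chosen in the arm not being compared. The mean R1881 response of 1428 induced genes was 1.036 ± 0.00943 times that of the control with SRF siRNA, and of 1296 repressed genes 1.075 ± 0.0240 times (ratio ± SE, exact two-sided permutation p = 0.29 and 0.005, 400 arrangements, smallest possible p 0.005). Each permutation p beside a ratio tests the difference of the responses. Arrangements that exchange the arms in 1 treatment carry the average siRNA effect, so a high p does not show equal responses. With Nkx2-5 siRNA the ratio was 0.959 ± 0.0108 for 1415 induced genes and 1.082 ± 0.0306 for 1370 repressed genes (exact permutation p = 0.585 and 0.61). For the induced genes the difference of responses was -0.0731 log2. Their vehicle scores were 2.59 to 2.604 with Nkx2-5 siRNA and 2.336 to 2.373 with control siRNA. With each siRNA arm's mean removed before permutation, a setting chosen after the data were seen, the permutation p was 0.005 and 0.01 for induced and repressed genes with SRF siRNA, and 0.005 and 0.03 with Nkx2-5 siRNA. On the 30 preset androgen-induced genes the ratio was 0.827 ± 0.01004 with Nkx2-5 siRNA (mean log2 responses of 3.18 and 3.84, exact permutation p = 0.005) and 0.964 ± 0.0120 with SRF siRNA (3.70 and 3.84, exact permutation p = 0.015). On the 9 preset androgen-repressed genes it was 0.894 ± 0.0420 with SRF siRNA and 0.924 ± 0.0550 with Nkx2-5 siRNA (exact permutation p = 0.015 and 0.6). Over these 8 tests the Benjamini-Hochberg adjusted p was 0.464, 0.02, 0.61 and 0.61 for the 4 large sets in the order given. It was 0.02 and 0.03 for the preset induced genes and 0.03 and 0.61 for the preset repressed genes. For repressed genes with SRF siRNA the ratio lay above 1 on the large set and below 1 on the preset list, and it was 1.002 (exact permutation p = 0.955) when the genes were chosen in the control libraries. A choice in the control libraries tends to lower the ratio by selection alone, so that value does not show which direction holds. Among the 1415 induced genes the interaction with Nkx2-5 siRNA called 306 with a smaller and 195 with a larger response. The other sets leaned the other way, with 130 smaller and 258 larger among the 1370 repressed genes. With SRF siRNA 94 were smaller and 158 larger among the 1428 induced genes, and 66 and 210 among the 1296 repressed genes.

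The knockdowns were set against each other across genes, with the caution that both share the control libraries. In vehicle the log2 fold changes of the SRF and Nkx2-5 siRNA effects correlated at r = 0.102 (rho = -0.077), with covariance 0.0243. Groups simulated without any change against the same controls gave a mean r of 0.448 and a covariance of 0.0281 over 20 simulations. In vehicle 386 genes were higher and 455 lower in both, against 481 and 532 for independent lists, and 1823 moved in opposite directions, against 1012. In R1881 the correlation was r = 0.2405 (rho = 0.237), with covariance 0.0626 against 0.0294 in simulations (simulated r 0.465). There 794 genes were higher and 1024 lower in both, against 481 and 587, and 1005 opposite, against 1062. The 3 control libraries of a treatment cannot be split into parts of 2 libraries each, so part of any same-direction excess may come from the shared controls. In the simulations shared controls gave a positive r, which argues against them as the source of the opposite excess in vehicle. Pairs that share no library gave r = -0.037 (SRF in vehicle with Nkx2-5 in R1881) and 0.045 (SRF in R1881 with Nkx2-5 in vehicle). In the first of these pairs 1637 genes were opposite, against 1072 for independent lists, 413 higher in both (against 483) and 603 lower (against 594). In the second 1294 were opposite, against 1003, 548 higher in both (against 478) and 748 lower (against 525). Between treatments, 962 genes were higher and 1111 lower with SRF siRNA in both vehicle and R1881 and 150 opposite, and 1883, 2394 and 480 with Nkx2-5 siRNA.

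Some named genes belong to families of near-identical or related sequence, so their split of reads is uncertain, to a degree that was not measured. They include the actins ACTA1, ACTA2, ACTB, ACTG1 and ACTG2, the kallikreins KLK2 and KLK3, the UGT2B genes and pseudogenes, ORM1 with ORM2, and TUBA3D. The interferon genes of the IFIT, IFITM and OAS families, the ribosomal protein genes with their processed pseudogenes, and RN7SL838P with RN7SL2 belong here too. Other named genes may be affected.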

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

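Tests chosen only after the result was seen are those of interferon genes, scaling, RN7SL2, the fit on protein-coding genes alone, the removal of the siRNA mean, the calls among genes with AGAGCAA and its place in the NKX2-5 transcripts.

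The difference of R1881 effects called 1457 genes for SRF against control siRNA, 3584 for Nkx2-5 against control and 4193 for SRF against Nkx2-5, each drawing attention as a difference between siRNA arms. For the first, 2 of 100 random splits of the libraries within treatments (of 200 possible) gave as many genes, the real one included, and the highest other gave 2086. For the Nkx2-5 difference 4 of 100 did, with 4146 as the highest other, and for SRF against Nkx2-5 5 of 100 did, with 5690 as the highest other. The larger splits point to a structure of the samples, since they mix siRNA arms and so carry the average siRNA effect. The split that exchanges the arms in 1 treatment equals that effect, 6497 genes for SRF and 8863 for Nkx2-5 against control, and was not among those drawn, so whether chance is excluded stays undecided for these differences. For the 7 comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. In each, 1 split, the real one, reached the real count, 10314, 10690 and 10575 for R1881 with control, SRF and Nkx2-5 siRNA, 4670 and 4629 for SRF siRNA and 7234 and 7679 for Nkx2-5 siRNA in vehicle and R1881, and the highest other gave 0, 1, 0, 1, 0, 0 and 0.

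Nkx2-5 siRNA changed 7234 and 7679 genes in vehicle and R1881, while NKX2-5 had 0 counts in the control and Nkx2-5 siRNA libraries. Of the 7-base sequences in 3' untranslated regions, AGAGCAA was tied most strongly to lower expression in vehicle (z = -8.34 over 2154 genes, -0.111 log2 on average; most positive sequence 4.51) and in R1881 (z = -7.03). These lie below every rearrangement of its letters (-5.83 and -4.03) and SRF siRNA gave 0.889 and 0.724, so pairing by a seed in the Nkx2-5 pool is a candidate explanation for part of the calls. AGAGCAA occurs in 1 of 4 NKX2-5 transcripts (its reverse complement in 0). Of genes with it, 794 (36.9%) were called lower in vehicle, against 23.5% of genes without it, so 794 is not a count of paired targets. The siRNA sequences are not given in the sources used here. A trend on GC content or length is argued against as the whole cause. The share of genes called at least 2-fold that remained after the trend's removal was at least 0.8536 in both treatments. An interferon response to the siRNA cannot be told apart from the rest: the lower of its medians against control was 0.892 log2, but SRF siRNA raised the list too and the direct contrast of Nkx2-5 with SRF siRNA, with 9 higher and 3 lower in vehicle and 7 and 3 in R1881, had an upward direction by camera at p = 0.0374 and 0.0617 (0.279 and 0.335 with an estimated correlation), while loss of NKX2-5 below the detection limit stays open and untested.

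The R1881 response of the 30 preset androgen-induced genes was 0.827 of control with Nkx2-5 siRNA (exact permutation p = 0.005, Benjamini-Hochberg adjusted p = 0.02 over 8 tests). With this siRNA more of these genes were called higher than lower in vehicle, and most were called lower in R1881. The ratio does not separate a raised vehicle level from a lowered R1881 level. Scaling is argued against, since the ratio was at most 0.8325 with RLE factors or on protein-coding genes alone. The seed pairing above and an effect of Nkx2-5 itself stay open, and neither was tested on these genes. The ratio over 1415 genes chosen in the SRF arm was 0.959, with exact permutation p = 0.585 as planned and 0.005 after removal of the siRNA mean. The planned permutation carries the average siRNA effect, so its p cannot decide whether the responses were equal. On protein-coding genes alone it was 0.9862 (exact permutation p = 0.665). With genes chosen in the control libraries it was 0.9211 (exact permutation p = 0.155), but that choice tends to lower the ratio by selection alone. Whether the smaller response reaches beyond the preset list therefore stays open.

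Libraries with SRF siRNA held more counts of the chromosome 21 ribosomal RNA region, and 0.136 to 0.235% mitochondrial ribosomal RNA. Poorer capture of all abundant structured RNAs is argued against, since the signal recognition particle RNA RN7SL2 was not higher (log2 fold changes of -0.0345 ± 0.0947 and -0.079 ± 0.0947). A carry-over of ribosomal RNA reads into the SRF siRNA calls cannot be told apart from the rest. A share of 0.968 of the protein-coding genes called in vehicle remained when the other genes were left out of the fit, but that fit keeps the counts of these genes and moved their fold changes by a median of 0.0161 log2. RNA quality, and an effect of SRF on ribosomal RNA, stay open and were not tested.

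Ratios of R1881 responses that differed between arms by exact permutation were 1.075 for repressed genes with SRF siRNA, and 0.964, 0.894 and 0.827 for the preset induced and repressed genes with SRF siRNA and the preset induced genes with Nkx2-5 siRNA.

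For SRF against control siRNA, genes with higher R1881 effects, among those with at least 50 counts in the highest group, were AOC1 (2.89), NPPC (1.93), SOX9 (1.77), VAV3 (1.75), ADRA2A (1.65), ATP10D (1.61), SUSD2 (1.47) and MAF (1.45). Lower effects among them were those of ACTA2 (-4.56), MCPH1-AS1 (-3.34), UGT2B25P (-2.70), COL3A1 (-2.54), REP15 (-2.40), IGF1 (-2.37), C8orf4 (-2.33) and RN7SL838P (-2.25). List members were ACTA2 (-4.56), TPM4 (-0.86) and FLNA (-0.75) of the actin genes, CDC6 (-0.52), RRM2 (-0.67) and MCM10 (-0.63) of replication, and NUSAP1 (-0.65), CENPF (-0.79) and BUB1B (-0.69) of mitosis. Of these, AOC1 lost its call in 8 of 18 other settings (edgeR quasi-likelihood adjusted p 0.0328 to 0.162), NPPC without control siRNA vehicle replicate 2 or SRF siRNA vehicle replicate 1 (at most 0.0607), and COL3A1 without control siRNA R1881 replicate 1 or SRF siRNA R1881 replicates 2 or 3 (at most 0.19). UGT2B25P lost it without SRF siRNA vehicle replicate 3 (adjusted p = 0.0611, range from 0.000696) and REP15 without SRF siRNA vehicle replicate 2 (0.0993, range from 0.00162), both by edgeR.

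For Nkx2-5 against control siRNA, higher R1881 effects were those of the mitochondrial ribosomal RNA MT-RNR1 (4.34, which became -0.425 without control siRNA vehicle replicate 3), AOC1 (3.64), MMP7 (3.35), MMP10 (2.90), VSTM2L (2.68), ARHGAP20 (2.58), NLRC5 (2.53) and DAPK1 (2.45). Lower ones were those of ACTG2 (-4.84), CHRNA2 (-3.21), SPRY4 (-3.21), MMP12 (-3.18), MYL9 (-2.88), F5 (-2.85), MOGAT2 (-2.60) and MCM10 (-2.23). List members were HERC3 (-1.55) and SLC45A3 (-1.32) of the androgen-induced genes, MCM10 (-2.23), RRM2 (-1.84) and MCM7 (-0.88) of replication, and NUSAP1 (-1.66), KIF20A (-1.43) and BUB1B (-1.72) of mitosis. ACTG2 and MMP12 had 0 counts with control siRNA in vehicle, so their values depend on the model's default prior count, and MMP12 lost its call in 9 of 19 other settings (edgeR or DESeq2 adjusted p 0.0248 to 0.11).

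For SRF against Nkx2-5 siRNA, higher effects were those of CARTPT (4.26), ORM1 (3.52), SPRY4 (3.29), MOGAT2 (3.28), TUBA3D (3.09), SERPIND1 (3.03), DEFB132 (2.26) and TENM1 (2.25). Lower ones were those of MCPH1-AS1 (-5.39), MMP10 (-5.10), UGT2B24P (-4.98), GLIPR1 (-3.66), C8orf4 (-3.63), UGT2B11 (-3.52), ACTA2 (-3.51) and ACTA1 (-3.50). List members were HERC3 (1.62), ELL2 (1.44) and TMPRSS2 (1.01) of the androgen-induced genes, ACTA2 (-3.51), TPM4 (-1.43) and FLNA (-1.56) of actin, KIF20A (1.02), NUSAP1 (1.01) and CDC20 (1.29) of mitosis, and CDKN1A (0.72), RRM2B (0.77) and BTG2 (0.67) of the p53 targets. ORM1 had 1 count with SRF siRNA in vehicle, UGT2B24P 0 and 3 with Nkx2-5 and SRF siRNA in vehicle, and ACTA1 3 with SRF siRNA in R1881, so their values depend on the model's default prior count. ORM1 lost its call without Nkx2-5 siRNA vehicle replicate 2 or SRF siRNA vehicle replicate 1 (edgeR adjusted p at most 0.114), UGT2B24P without any Nkx2-5 siRNA vehicle library or SRF siRNA vehicle replicates 1 or 2 (at most 0.168), and ACTA1 without SRF siRNA vehicle replicate 1 (0.148, range from 0.00186).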

How the results depend on the processing

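The use of protein-coding genes alone and removal of the siRNA mean before permutation were chosen after the data were seen, and the other settings before. With a 2-fold minimum the counts of called genes were 2787, 3241 and 3012 for R1881 with control, SRF and Nkx2-5 siRNA, 348 and 367 for SRF siRNA and 843 and 1156 for Nkx2-5 siRNA in vehicle and R1881, and 144, 534 and 633 for the differences of SRF, of Nkx2-5 and between them, by construction of the minimum. No other setting moved the total of called genes in a comparison by over 1.5 times. Without the low-count filter the prior degrees of freedom were infinite (11.05 with it), so each gene took the spread of the trend and none of its own, and p-values of that setting carry less weight. The lowest count for SRF siRNA in vehicle was 3332, with only the groups compared in the fit. Induced genes with SRF siRNA gave a ratio of 1.07 (exact permutation p = 0.025) with no fold minimum, 0.964 (p = 0.015) on the preset list, 0.9969 (p = 0.885) when chosen in the control libraries and 1.036 (p = 0.005) after removal of the siRNA mean. Repressed genes with SRF siRNA gave 0.894 (exact permutation p = 0.015) on the preset list, the opposite direction, and 1.002 (p = 0.955) when chosen in the control libraries. Induced genes with Nkx2-5 siRNA gave 0.827 (exact permutation p = 0.005) on the preset list, 0.9862 (p = 0.665) on protein-coding genes alone, 0.9211 (p = 0.155) when chosen in the control libraries and 0.959 (p = 0.005) after removal of the siRNA mean. Repressed genes with Nkx2-5 siRNA gave 1.006 (exact permutation p = 0.885) when chosen in the control libraries and 1.082 (p = 0.03) after that removal. A choice of genes in the control libraries tends to lower the ratio by selection alone, so those ratios do not show a direction. Removal of the siRNA mean left the ratios as they were and changed only the p, since the planned permutation carries the average siRNA effect. The cause of the other shifts was not tested. Of 190 list tests camera called 95 with the preset and 56 with an estimated correlation, and fry called 135 for direction and 155 for change either way. With a filter of at least 1 CPM the correlation of the knockdown effects was 0.0762 in vehicle (from 0.102) and 0.222 in R1881 (from 0.2405), on fewer genes, for a cause not tested.

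Leaving out 1 library at a time gave 9596 to 9821 called genes for R1881 with control siRNA, 10002 to 10379 with SRF siRNA and 9850 to 10177 with Nkx2-5 siRNA. The ranges were 3564 to 4396 and 3412 to 4375 for SRF siRNA, 6306 to 6937 and 6863 to 7180 for Nkx2-5 siRNA in vehicle and R1881, and 1095 to 1644, 3044 to 3495 and 3652 to 4216 for the differences of SRF, of Nkx2-5 and between them. Ratios ranged from 1.030 to 1.042 (exact permutation p 0.19 to 0.405) and 1.056 to 1.088 (p 0.005 to 0.02) for induced and repressed genes with SRF siRNA. With Nkx2-5 siRNA they ranged from 0.952 to 0.964 (exact permutation p 0.58 to 0.695) and 1.061 to 1.102 (p 0.715 to 0.81). These planned permutations carry the average siRNA effect too, so their high p do not show equal responses. Of 27247 values of named genes under other settings, 26117 kept their direction and side of the threshold, 1129 kept their direction and lost the call, and 1 turned. MT-RNR1, a mitochondrial ribosomal RNA, had a higher R1881 effect with Nkx2-5 than control siRNA (4.34). Without 1 library it ranged from -0.425 to 4.913. The value of -0.425 (edgeR adjusted p = 0.398, range from 0.00213 over left-out libraries) came without control siRNA vehicle replicate 3, the library with 0.494% mitochondrial ribosomal RNA. The call was also lost without control siRNA R1881 replicates 1 or 2 (4.25 and 4.31), Nkx2-5 siRNA vehicle replicates 1 or 2 (4.305 and 4.25) or Nkx2-5 siRNA R1881 replicate 2 (4.29), with adjusted p of at most 0.0599.

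Replicate numbers did not pair the samples, since deviations of same-numbered libraries correlated at -0.141 to 0.131 (mean -0.005 over 45 pairs). With the replicate number as a block, counts were 10226, 10637 and 10525 for R1881, 4515, 4533, 7153 and 7546 for the siRNA effects, and 1348, 3467 and 4102 for the differences. The block also ended the call of MT-RNR1 (3.74, edgeR adjusted p = 0.0719). With differences taken within replicate numbers all 4 scores over the large sets had exact permutation p = 0.1, the smallest that 6 differences allow, at the same ratios, so this setting cannot pass 0.05. The depth sets a floor of 0.131 to 0.221 CPM per library, below which NKX2-5 lies.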

Other observations

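Chosen only after the results were seen were the comparison of GCTAGTA and TGCTAGT across treatments and the choice of lists described here. With SRF siRNA, cholesterol synthesis genes rose in 3 and fell in 3 of 20 cases in vehicle and rose in 4 and fell in 2 in R1881 (3 and 3, and 5 and 2, adjusted over the list alone), with HMGCS1 at -0.62 ± 0.06 and -0.39 ± 0.05. Fatty acid synthesis genes rose in 3 and fell in 1 of 13 cases in vehicle and rose in 1 and fell in 6 in R1881, as over the list alone, with the desaturase gene SCD at -0.27 ± 0.05 and -0.40 ± 0.05 (camera adjusted p = 0.868 and 0.0457, and 0.936 and 0.195 with an estimated correlation). With Nkx2-5 siRNA SCD rose in both, by 0.60 ± 0.05 and 0.77 ± 0.05, while the list split into 5 higher and 3 lower in vehicle and 5 and 4 in R1881, as over the list alone (camera adjusted p = 0.145 and 0.764). The p53 targets, higher with Nkx2-5 siRNA, were 3 higher and 3 lower of 17 with SRF siRNA in vehicle (1 and 6 without the low-count filter, 2 and 1 without control siRNA vehicle replicate 3, 1 and 2 without SRF siRNA vehicle replicate 3) and 6 higher and 2 lower in R1881 (3 and 4, and 6 and 4, over the list alone), with camera adjusted p = 0.939 and 0.192.

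Luminal markers in R1881 with Nkx2-5 siRNA moved both ways, 4 higher and 6 lower of 11 (4 and 7 over the list alone, camera adjusted p = 0.329). The prostate homeobox gene HOXB13 (-0.65 ± 0.04) and the epithelial factor gene GRHL2 (-0.49 ± 0.04) fell, and the keratin gene KRT8 rose (0.47 ± 0.05). With SRF siRNA in R1881 the epithelial adhesion gene EPCAM rose by 0.23 ± 0.04 and 8 of 11 markers were not called (2 higher and 1 lower, as over the list alone). ENO2, counted among neuroendocrine markers and also a glycolytic enzyme, rose with Nkx2-5 siRNA in R1881 (0.87 ± 0.09). Leukocyte markers rose in 4 of 5 tested cases with Nkx2-5 siRNA in R1881, as over the list alone, with the lysozyme gene LYZ at 2.77 ± 0.35 (camera adjusted p = 0.0422, and 0.105 with an estimated correlation).

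In 3' untranslated regions the sequence most strongly tied to lower expression with SRF siRNA in vehicle was GCTAGTA (z = -6.37 over 630 genes, lowest rearrangement of its letters -3.92). In R1881 it ranked 18 (z = -3.89), above a rearrangement of its letters at -4.54, and AAGAGTA led (z = -5.02). TGCTAGT, the same sequence shifted by 1 base, ranked 2 in vehicle (z = -5.27) and 3 in R1881 (z = -4.69). GCTAGTA occurs in 0 of 1 SRF transcripts. For orientation, 100 permutations of the Nkx2-5 siRNA fold changes in vehicle gave values from -4.63 to 5.51. SRF siRNA fold changes were not permuted.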
